A study of Homo sapiens with 6 samples.

How the data were processed

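Gene expression in 6 samples of SH-SY5Y cells was compared, 3 infected with a control vector and 3 with a vector labelled as overexpressing CDKN2B-AS1. Per the labels' protocols, RNA was isolated with a small-scale column kit, cDNA was made with a SMART-seq kit for low input, and libraries were read as paired ends. The submitters' processing notes name STAR 2.7.9, featureCounts 2.0.1, GRCh38.p13 and hg38, without stating the options. Whether assignment used strand is not given in the sources used here, so overlapping genes on opposite strands were treated as not separable. The column names of the groups carry different tags, LVx2 for the labelled overexpression and LVx1 for the control vector, that no label explains. A difference in handling that they mark, such as in the amount of vector, cannot be told apart from the difference between the groups.

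The deposited table holds FPKM per gene and library, with gene lengths and positions, per the file headers. FPKM multiplied by gene length in kilobases summed to 1e+06 in each library, and every library's values were multiples of 0.01 of a common step within a tolerance of 0.001 fragments for values up to 1000 fragments, in 100% of the values. The authors' fragment numbers therefore hold fractions, with 44.2% to 49.0% of the values whole, and the depth was recovered as 45102020, 29048596 and 43413832 fragments in control vector replicates 1, 2 and 3 and 27525077, 20466583 and 48996425 in labelled overexpression replicates 1, 2 and 3. Since the values are normalised and the fragments fractional, no count model served as the main test, and the test for logged values was used as planned for FPKM. Coordinates are those of the table. Of its 60612 gene IDs 58300 were found in the GENCODE v29 annotation of GRCh38, and 99.9% of these overlapped the annotated position. Gene lengths for trends came from transcripts of that annotation, which gave a value for 98.6% of the tested genes, 100% of the ribosomal protein list and 96.3% of the histone list. Names that stand on more than a single row (140) and 44 rows of the pseudoautosomal copy on Y were kept as deposited, and 3717 of 19942 protein-coding genes were listed at 0 in all libraries. The table used here holds 0 genes of the mitochondrial chromosome.

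Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a mean-variance trend in the moderated test (limma-trend), no block and no other covariate, and Benjamini-Hochberg adjustment over the 13984 tested genes at 0.05. Fold changes are on that log2 scale, are given as labelled overexpression minus control vector, and understate the changes of low genes. CDKN2B-AS1 lies below the filter and was fitted beside the tested genes, with an exact two-sided permutation test. The groups, test and filter, the gene lists and the rule for named genes were fixed before the data were examined. Named were CDKN2B-AS1, its 9p21 neighbours, the 12 largest rises and 12 largest falls among genes that passed, had a mean of at least 5 FPKM in a group and did not overlap between groups, and up to 4 members of smallest p of each list, of which a few are not reported here. Of the genes overlapping a named gene, those that passed the test are named with it, and others only in part.

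There were 31 lists, 27 of them with at least 5 tested genes: 9p21 neighbours, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, unfolded protein response, ATF4 and amino acid response, heat shock, oxidative stress (NRF2), hypoxia and glycolysis, interferon response, NF-kB and inflammation, immediate early genes, sterol and fatty acid synthesis, nuclear respiratory chain, cytosolic ribosomal proteins, adrenergic and mesenchymal neuroblastoma identity, synapse and neuronal excitability, neurite and cytoskeleton, axon guidance, Polycomb subunits, HOX genes, autophagy and lysosome, cell adhesion and matrix, replication-dependent histones and fibroblast markers. Epithelial, immune, and Schwann and glial markers and mitochondrially encoded mRNAs had too few. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists, and again with an estimated correlation and with fry, whose directional test asks whether a list's genes move on balance and does not compare them with other genes.

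Data were simulated for the overexpression against control vector comparison, over 13984 genes with the libraries' residual spread and depth. The changed genes were all drawn from those with a mean of at least 5 FPKM, so recovery of lower genes was not tested. The fit recovered 25 of 50 genes changed 1.5-fold, 48 of 50 changed 2-fold, and 50 of 50 changed 3-fold and 4-fold. Of its 193 calls 20 were false, so the realised false discovery share exceeded the nominal level. A list shifted by a known amount passed camera and 0 of 26 unshifted lists did. Genes were simulated as independent, so this does not show how camera performs on lists whose genes vary together. In the data the estimated correlation was 0.33 in the ribosomal protein list and 0.14 in the histone list. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the moderation, a fold minimum and leaving out each library. Added after the data were seen were limma-voom on the recovered fragments and the removal of per-library trends on transcript length or GC content, fitted by loess (span 0.4) without ribosomal protein and histone genes. Medians of lists in the tests of explanations carry 95% bootstrap intervals from 2000 draws over genes. These intervals treat genes as independent and carry no spread between libraries.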

Results

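RNA was measured in SH-SY5Y, a human neuroblastoma cell line with a neuronal-type expression programme, after infection with a control vector or with a vector labelled as overexpressing CDKN2B-AS1, a long noncoding RNA transcribed antisense to the CDKN2B tumour suppressor gene on chromosome 9. Each group held 3 libraries, 6 in all. The deposited table gave FPKM, fragments scaled to gene length and to each library's total of assigned fragments, for 60612 genes. The depth recovered from those values ran from 29048596 to 45102020 fragments in the control vector libraries and from 20466583 to 48996425 in the labelled overexpression libraries. Between 13530 and 13754 genes per control vector library reached 1 FPKM, and 13913 to 13965 per labelled overexpression library. FPKM summed over all genes ran from 381310 to 400215 and from 349703 to 365333, so both measures separated the groups. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The control vector libraries correlated with each other at Pearson r of 0.959 to 0.968 across the 13984 tested genes the labelled overexpression libraries at 0.975 to 0.983, and libraries of different groups at 0.959 to 0.969. The control vector libraries were thus no closer to each other than to the other group, and control vector replicate 3 stood apart on the second principal component (26.3% of the variance) at -40.6, against -4.86 to 17.8 in the others. The groups separated on the first (31.5%). Genes are not independent replicates in such a correlation.

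The comparison addressed which transcripts differ when CDKN2B-AS1 is overexpressed. CDKN2B-AS1 itself (ENSG00000240498, GRCh38 chromosome 9, 21994139 to 22128103, plus strand) was little higher in the libraries labelled as overexpressing it. Its level was 0.272, 0.288 and 0.191 FPKM in control vector replicates 1, 2 and 3 and 0.338, 0.304 and 0.353 FPKM in the labelled overexpression replicates 1, 2 and 3. The means were 0.250 ± 0.0522 and 0.332 ± 0.0252 FPKM (SD, n = 3 each), a ratio of 1.33. All 3 labelled overexpression libraries lay above all 3 controls, which gives p = 0.1 in the exact two-sided permutation test, the smallest value that 3 libraries against 3 allow. In limma-trend on log2(FPKM + 0.5) the log2 fold change was 0.15 (SE 0.29, Benjamini-Hochberg adjusted p = 0.834), a scale that understates changes of low genes. These levels rested on 127.08 to 353.42 fragments per library, and limma-voom on the recovered fragments, added after the data were seen, gave 1.36-fold with a 95% interval of 0.91 to 2.03. Because the targeted RNA differed so little, the groups are named below by their labels, and every direction given is that of the libraries labelled overexpression against those labelled control vector.

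Of the 11 listed neighbours of CDKN2B-AS1 on 9p21, 6 were high enough to test and 0 passed. CDKN2A, which encodes the cell cycle inhibitors p16INK4a and p14ARF, stood at 5.60 ± 1.23 FPKM in control vector and 4.42 ± 0.711 FPKM in labelled overexpression libraries (SD, n = 3 each), with a limma-trend Benjamini-Hochberg adjusted p of 0.476. The 3 labelled overexpression libraries were below the 3 controls for KLHL9, a substrate adaptor of a ubiquitin ligase, at 8.16 ± 0.738 against 10.9 ± 1.55 FPKM (SD, n = 3 each), without passing the test (limma-trend, Benjamini-Hochberg adjusted p = 0.242). FOCAD, MTAP, MLLT3 and ELAVL2 had log2 fold changes of 0.06, -0.17, -0.36 and -0.18. CDKN2B, which encodes the inhibitor p15INK4b, lay near the detection limit, with 23 fragments summed over the controls and 10 over the labelled overexpression libraries. The depth-scaled ratio of those sums was 0.527, with an exact 95% binomial interval of 0.224 to 1.15 that covers counting error only and does not exclude equal levels. The 3 labelled overexpression libraries, at 0.0250, 0.0275 and 0.0264 FPKM, lay below the 3 controls at 0.0568, 0.0409 and 0.0475 FPKM. Such separation, seen for KLHL9 as well, is not rare here: the groups did not overlap in 24.1% of the tested genes, against the 10% that chance gives. DMRTA1, IFNE, CDKN2A-DT and HACD4 were listed at 0 in all 6 libraries. As a list the neighbours had a median log2 fold change of -0.24, with 0 members past the threshold when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.137). The list passed downward in 1 of 17 alternatives, without a filter on low values, with a median of -0.18 (camera, Benjamini-Hochberg adjusted p = 0.0189). It did not pass there with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.155).

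**Figure D1:**
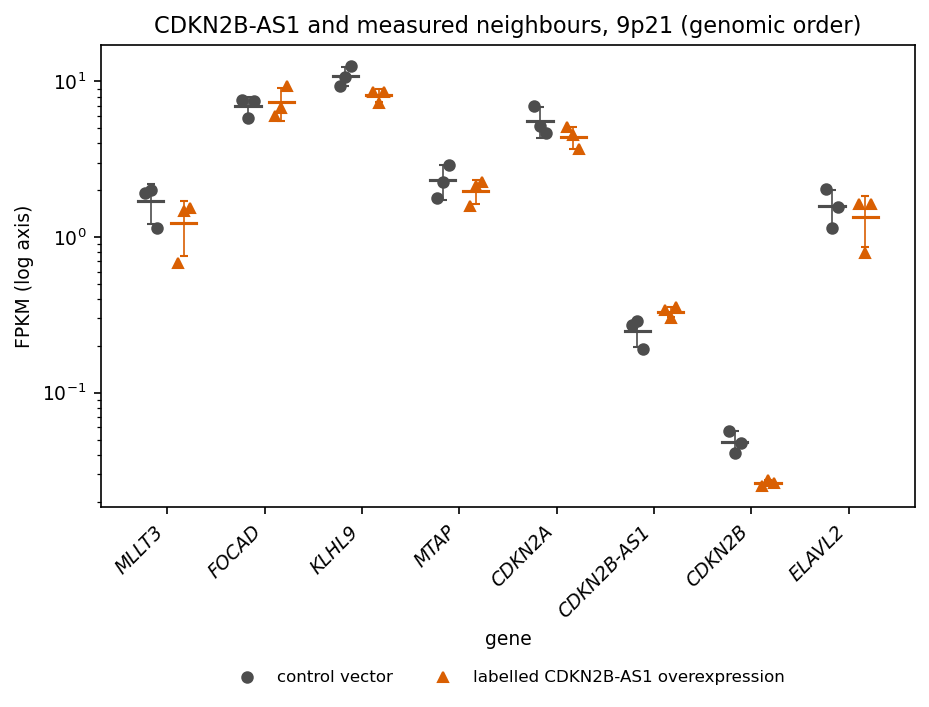
FPKM on a log axis of CDKN2B-AS1 and of the neighbouring 9p21 genes above 0 in all libraries, in genomic order. Symbols are single libraries, lines are group means and bars are SD (n = 3); CDKN2B-AS1 means were 0.250 and 0.332 FPKM.

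Across the transcriptome, FOS, an immediate early transcription factor of the AP-1 complex, had the largest fall. It stood at 27.0 ± 17.1 FPKM in control vector and 1.56 ± 0.314 FPKM in labelled overexpression libraries (SD, n = 3 each). The control vector mean rested on replicate 3, at 46.6 FPKM against 15.8 and 18.5 FPKM in replicates 1 and 2, and without replicate 3 the log2 fold change was -3.11 (limma-trend, Benjamini-Hochberg adjusted p = 0.00146). Messages for the secreted proteins LTF, an iron-binding glycoprotein, and SERPINF1, a serpin known as PEDF, fell as well, from 5.46 ± 1.33 to 1.17 ± 0.303 FPKM and from 11.1 ± 0.519 to 4.96 ± 0.125 FPKM (SD, n = 3 each). CCND1, the G1 cyclin D1, rose 2.22-fold from 57.1 ± 3.73 to 128 ± 22.4 FPKM, and NEFM, the medium neurofilament subunit, rose 2.39-fold from 23.5 ± 2.90 to 57.7 ± 14.2 FPKM (SD, n = 3 each). The proliferation marker MKI67 rose 2.19-fold from 6.10 ± 1.48 to 13.8 ± 0.923 FPKM.

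In limma-trend with Benjamini-Hochberg adjustment, 159 of 13984 genes passed an adjusted p of 0.05, with 74 higher and 85 lower in the labelled overexpression libraries. The log2 fold change was -3.58 for FOS (SE 0.35, adjusted p = 0.0150), -1.83 for LTF (SE 0.24, adjusted p = 0.0215) and -1.09 for SERPINF1 (SE 0.14, adjusted p = 0.0215). For CCND1 it was 1.15 (SE 0.13, adjusted p = 0.0215), for NEFM 1.26 (SE 0.17, adjusted p = 0.0224) and for MKI67 1.13 (SE 0.18, adjusted p = 0.0332) in the same limma-trend test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2477 genes, against 699 given by chance, and the groups did not overlap in 3376 genes, 24.1% against the 10% that chance gives. The median size of the 74 rises was 0.81 and that of the 85 falls -0.67 on the log2 scale. Of the falls, 22 were cytosolic ribosomal protein genes, 8 were listed histone genes and 12 were ribosomal protein pseudogenes.

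The number of calls depended on single libraries and on the scaling. It was 3 without control vector replicate 1, 0 without control vector replicate 2, 139 without control vector replicate 3, and 0, 0 and 3 without labelled overexpression replicates 1, 2 and 3, while 2274, 1689 and 1612 genes had an unadjusted limma-trend p under 0.05 in the settings with 0 calls. FOS kept a log2 fold change of -3.87 to -3.11 with any library left out, with a limma-trend Benjamini-Hochberg adjusted p of up to 0.0754. With values rescaled to a common total per library, the split was 167 higher and 51 lower and the median over all tested genes moved from 0.05 to 0.17, with median-of-ratios factors it was 59 higher and 119 lower, and array weights gave 149 higher and 116 lower.

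ST8SIA2, a polysialyltransferase that modifies NCAM1, rose from 3.40 ± 0.737 to 7.61 ± 0.772 FPKM, FBXW8, an F-box protein, from 2.46 ± 0.821 to 5.89 ± 0.302 FPKM, and SEC14L1 from 5.29 ± 0.859 to 11.6 ± 2.703 FPKM (SD, n = 3 each). ACTA2, smooth muscle actin, rose from 3.44 ± 0.750 to 7.67 ± 0.693 FPKM, though its span overlaps STAMBPL1 and ACTA2-AS1 on the other strand. The globin gene HBQ1 fell from 9.86 ± 2.41 to 4.22 ± 0.147 FPKM. The noncoding CTD-2256P15.2 fell from 6.03 ± 0.795 to 2.54 ± 0.444 FPKM.

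Several of the other large changes are uncertain because the deposited values hold fractions of a fragment, as arise where fragments matching several genes are split between them. LTO1 overlaps CCND1, and GS1-72M22.1 overlaps NEFM, each on the other strand, with log2 fold changes of 1.03 and 1.04. EML4-AS1 overlaps EML4, a microtubule-binding protein gene that passed the test itself at 0.91, and had 1.15. The microRNA gene MIR573 lies within DHX15 and had 1.74, against 0.35 for DHX15, and CTD-2647L4.4 lies within HMBOX1 and had a fold of 2.15, against 0.69 on the log2 scale for HMBOX1. RP11-386I14.4, which overlaps DNAJB4, had -1.58. Overlapping genes on the other strand also passed for RPS3A (SH3D19 at -0.93), RRM1 (RRM1-AS1 at 0.56), VIM (VIM-AS1 at 0.82 and RP11-124N14.3 at 0.71) and ALDOC (RP11-192H23.5 at -0.77), so fragments of these pairs were not separable. COL4A2-AS1 passed at 0.80 over COL4A2, which did not. Among the falls, RPS3AP20 is a pseudogene of RPS3A with -1.05, CH17-268I9.2 is annotated as an immunoglobulin pseudogene and had -1.07, and the microRNA gene ENSG00000264063 had -1.68.

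**Figure D2:**
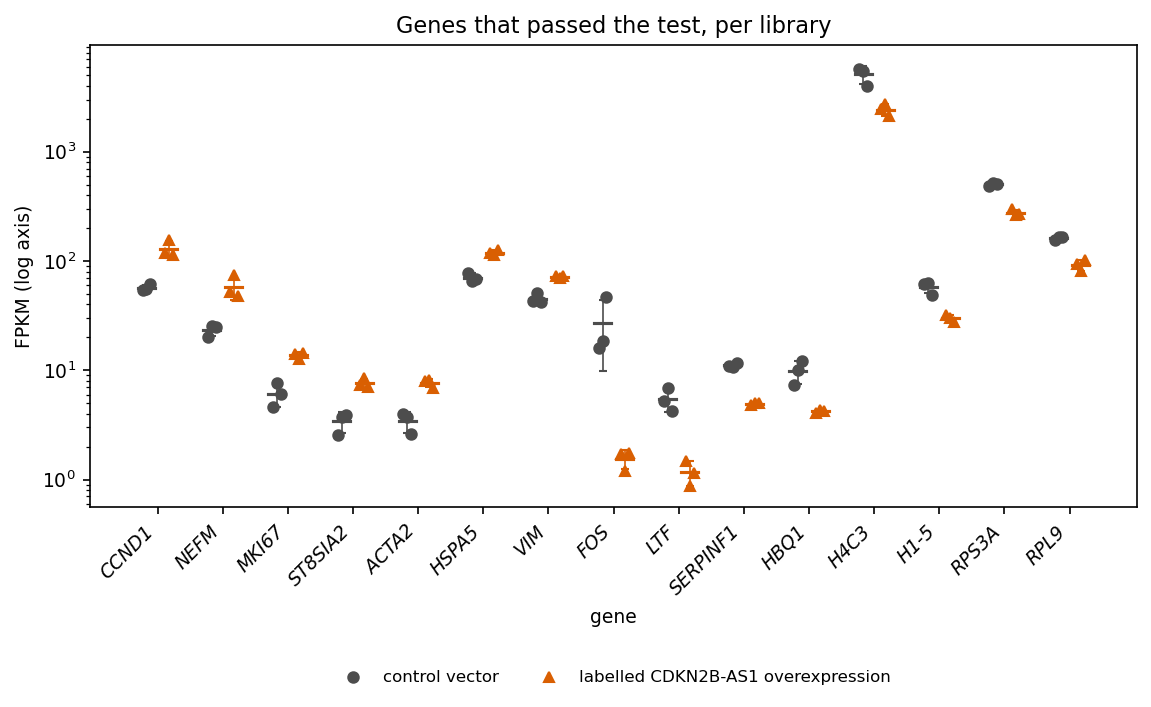
FPKM per library on a log axis for 15 genes that passed the limma-trend test; circles are control vector and triangles labelled overexpression libraries, with group mean and SD (n = 3). FOS lies at 27.0 against 1.56 FPKM on average, and CCND1 at 57.1 against 128.

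The genes of the cytosolic ribosome fell together. All 66 had log2 fold changes below 0 under the deposited scaling, with a median of -0.42, and 22 passed the test, 56 when adjusted over the list alone. RPS3A fell to 0.547 of its control vector level of 506 ± 16.7 FPKM, RPL9 from 162 ± 4.81 to 92.1 ± 10.7 FPKM, RPS18 from 1470 ± 82.1 to 906 ± 63.1 FPKM and RPL15 from 354 ± 5.48 to 230 ± 3.69 FPKM (SD, n = 3 each). The list passed with camera at its preset correlation (Benjamini-Hochberg adjusted p = 4.00e-45) and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0939). Its median stayed negative under each scaling.

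Replication-dependent histone genes, whose messages end in a stem-loop in place of a poly(A) tail, fell with a median log2 fold change of -0.46. Of the 27 tested, 8 were lower, 0 higher and 19 did not pass, and 12 were lower when adjusted over the list alone. H4C3 fell from 5094 ± 926 to 2418 ± 303 FPKM, H2AC20 from 25.1 ± 2.64 to 11.8 ± 2.104 FPKM, H4C11 from 20.2 ± 2.71 to 9.39 ± 2.12 FPKM, and the linker histones H1-5 and H1-3 from 57.8 ± 7.36 to 29.9 ± 2.35 and from 57.2 ± 6.30 to 31.8 ± 3.77 FPKM (SD, n = 3 each). Histone genes share sequence, so the values of single members are uncertain. The list's camera adjusted p was 3.76e-11 (Benjamini-Hochberg), and the adjusted p was 0.0939 with an estimated correlation.

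Nuclear genes of the respiratory chain were lower as a list, with a median of -0.20 and 0 of 45 members past the threshold over all genes, 11 lower when adjusted over the list alone. ATP5F1C, a subunit of ATP synthase, stood at 218 ± 13.7 against 161 ± 8.19 FPKM, and COX6A1, COX7A2 and COX4I1, subunits of cytochrome c oxidase, had log2 fold changes of -0.39, -0.38 and -0.35. For this list camera gave a Benjamini-Hochberg adjusted p of 5.89e-08, and the adjusted p was 0.0828 with an estimated correlation. With values rescaled to a common total the median was -0.09 (camera, Benjamini-Hochberg adjusted p = 1.12e-05), so how far the list fell depended on the scaling.

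Chaperones and folding enzymes of the endoplasmic reticulum, the unfolded protein response list, were higher, with a median of 0.44. HSPA5, the chaperone BiP, rose from 70.5 ± 6.32 to 119 ± 7.34 FPKM and HSP90B1 from 33.5 ± 0.573 to 49.1 ± 0.561 FPKM (SD, n = 3 each). The other 22 of 24 members did not pass over all genes, among them the disulfide isomerase genes PDIA3 and PDIA6 at 0.47 and 0.44, and 14 were higher and 1 lower when adjusted over the list alone. Camera's Benjamini-Hochberg adjusted p was 1.10e-07, and the adjusted p was 0.0828 with an estimated correlation.

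Neuronal cytoskeleton genes and replication genes also rose as lists. In the neurite and cytoskeleton list NEFM, NEFL, MAP1B and DPYSL2 were higher, 18 of 22 did not pass, and 10 were higher and 1 lower when adjusted over the list alone. NEFL, the light neurofilament subunit, rose from 56.7 ± 3.29 to 84.5 ± 8.39 FPKM and MAP1B, a microtubule-associated protein, from 28.9 ± 2.66 to 46.3 ± 3.95 FPKM, while DPYSL2 had 0.52 (SD, n = 3 each). The list's median was 0.34 (camera, Benjamini-Hochberg adjusted p = 3.22e-05, and adjusted p = 0.0828 with an estimated correlation). In the G1/S and DNA replication list UHRF1, a factor of maintenance DNA methylation, rose from 23.9 ± 2.17 to 44.3 ± 5.39 FPKM, RRM1, of ribonucleotide reductase, rose from 50.6 ± 3.44 to 75.9 ± 5.22 FPKM, and the flap endonuclease FEN1 rose 1.399-fold. MCM4, a subunit of the replicative helicase, had 0.46 without passing. The other 30 of 33 did not pass, 8 were higher when adjusted over the list alone, and the median was 0.31 (camera, Benjamini-Hochberg adjusted p = 4.08e-05, and adjusted p = 0.0957 with an estimated correlation).

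The lists of heat shock, of cell adhesion and matrix, and of synapse and neuronal excitability had medians of 0.25, 0.31 and 0.26, with 0 of 18, 0 of 22 and 0 of 20 members past the threshold over all genes and 2, 5 and 0 higher when adjusted over the list alone. HSPA4 and BAG3, a chaperone and a co-chaperone, had 0.57 and 0.66, with 0.26 for STIP1 and 0.33 for HSPA1A, whose paralog HSPA1B shares its sequence. The matrix genes TNC, COL4A2, NID1 and TIMP2 had 1.24, 0.57, 0.51 and 0.58. The nicotinic receptor subunits CHRNA3 and CHRNA5 had 0.38 and 0.88, with SV2C at 0.84. CHRNA5 overlaps CHRNA3 on the other strand, so their fragments were not separable. CHRNA5 stood at 6.95 FPKM in control vector replicate 3, within the 6.84 to 7.25 FPKM of the labelled overexpression libraries. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.000489, 0.00167 and 0.0385, and the adjusted p was 0.132, 0.0939 and 0.281 with an estimated correlation. The synapse list lost its call without control vector replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.155), without labelled overexpression replicate 2 (adjusted p = 0.0631), without a filter (adjusted p = 0.0544), without the trend (adjusted p = 0.0511) and with the transcript length trend removed (adjusted p = 0.0616).

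Fold changes rose with transcript length. Across tested genes Spearman's rho with transcript length was 0.22. That length was the median over a gene's annotated protein-coding transcripts, or over all its transcripts where none was protein-coding. The median log2 fold change ran from -0.06 in 1491 genes of up to 500 nucleotides to 0.23 in 1324 genes of over 4000. With that trend removed from each library, an alternative added after the data were seen, the medians were -0.44 for ribosomal protein genes, -0.49 for histones, -0.22 for the respiratory chain, 0.30 for the unfolded protein response, 0.24 for neurite and cytoskeleton, 0.22 for G1/S and DNA replication, 0.17 for heat shock, 0.22 for cell adhesion and matrix and 0.15 for synapse. Genes higher then numbered 48 and genes lower 115 in limma-trend with Benjamini-Hochberg adjustment.

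The other 17 tested lists besides the 9p21 neighbours did not pass camera. Among immediate early genes FOS alone passed, 1 was higher and 3 lower when adjusted over the list alone, and JUNB, IER2 and DUSP4 had -0.54, -0.44 and 0.73. That list's median was 0.12, its mean -0.20 and its camera direction down (Benjamini-Hochberg adjusted p = 0.330), and the median of the 16 members other than FOS was 0.16. In the G2/M and mitosis list MKI67 passed, FOXM1, PRC1 and MAD2L1 had 0.54, 0.63 and -0.61, 4 were higher and 1 lower when adjusted over the list alone, and the median was 0.10 (camera, Benjamini-Hochberg adjusted p = 0.149). In the mesenchymal neuroblastoma list the intermediate filament gene VIM rose from 45.2 ± 4.55 to 72.1 ± 2.01 FPKM, with ZEB1, LGALS1 and FN1 at 0.61, 0.23 and 0.53, a median of 0.23 over 13 genes and 1 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0739). In the adrenergic list 0 of 27 passed, NCAM1, GATA3, EYA1 and STMN2 had 0.67, 0.40, 0.63 and -0.25, 2 were higher when adjusted over the list alone, and the median was 0.13 (camera, Benjamini-Hochberg adjusted p = 0.176). In the hypoxia and glycolysis list the aldolase ALDOC fell from 37.8 ± 4.07 to 24.0 ± 1.92 FPKM, also when adjusted over the list alone, PDK1, ENO1 and SLC2A1 had -0.61, -0.26 and -0.33, and the median was -0.02 over 29 genes (camera, Benjamini-Hochberg adjusted p = 0.152).

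For the Polycomb subunits, complexes that CDKN2B-AS1 RNA is known to bind, 0 of 25 genes passed, also when adjusted over the list alone. EZH1, JARID2, PCGF3 and PHF19 had 1.21, 0.72, 0.51 and 0.44, and the median was 0.13 (camera, Benjamini-Hochberg adjusted p = 0.173). EZH1 was low, at 0.497 ± 0.285 FPKM (SD, n = 3) in control vector libraries. Of the HOX genes 7 of 35 were tested and 0 passed, also when adjusted over the list alone, with HOXD9, HOXC6, HOXD3 and HOXD8 at 0.31, 0.36, 0.23 and 0.38 and a median of 0.23 (camera, Benjamini-Hochberg adjusted p = 0.623). The p53 target list had 0 of 27 past the threshold and 1 lower when adjusted over the list alone, CCNG1 at -0.71. SUSD6, SESN1 and SPATA18 had 0.61, -0.43 and 0.94, with SPATA18 low at 0.480 ± 0.644 FPKM (SD, n = 3) in control vector libraries. The p53 list's median and mean were 0.03 while camera gave a downward direction (Benjamini-Hochberg adjusted p = 0.718). Apoptosis regulators had 0 of 20, also when adjusted over the list alone, with CASP2, BID and APAF1 at 0.47, -0.28 and 0.51, a median of -0.06 and a mean of 0.04 (camera, downward, Benjamini-Hochberg adjusted p = 0.830).

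Among the stress and metabolic lists, 0 of 26 genes of the ATF4 and amino acid response passed, also when adjusted over the list alone, with AARS1, SLC7A5, GARS1 and MTHFD2 at 0.40, 0.56, 0.33 and -0.35 and a median of 0.06 (camera, Benjamini-Hochberg adjusted p = 0.718). NRF2 targets had 0 of 23, and 3 higher and 2 lower when adjusted over the list alone, with NQO1, SOD2, GPX1 and FTL at 0.64, 0.65, -0.37 and -0.33 and a median of 0.02 (camera, Benjamini-Hochberg adjusted p = 0.829). Sterol and fatty acid synthesis had 0 of 31, also when adjusted over the list alone, with SREBF1, MSMO1, FDFT1 and ACSS2 at -0.76, -0.40, -0.27 and 0.41 and a median of -0.03 (camera, Benjamini-Hochberg adjusted p = 0.143). Autophagy and lysosome had 0 of 31 and 1 higher when adjusted over the list alone, CTSL at 0.63, with WIPI2 and LAMP1 at 0.43 and 0.63 and a median of 0.11 (camera, Benjamini-Hochberg adjusted p = 0.252). Axon guidance had 0 of 12 and 1 higher when adjusted over the list alone, PLXNA2 at 0.76, with SEMA3C, EFNA1 and PLXNA4 at 0.40, -0.37 and 0.57 and a median of 0.17 (camera, Benjamini-Hochberg adjusted p = 0.176). NF-kB targets had 0 of 8 and 2 higher when adjusted over the list alone, TRAF1 and SOD2 at 1.33 and 0.65. TRAF1 was low, at 0.0149, 0.846 and 1.06 FPKM in control vector replicates 1, 2 and 3, so its value depends on the pseudocount. ICAM1 and CCL2 had 0.45 and -0.30, and the NF-kB list had a median of 0.29 (camera, Benjamini-Hochberg adjusted p = 0.152). Interferon-stimulated genes had 0 of 14, also when adjusted over the list alone, with IFITM3, IFITM2 and HERC5 at -0.79, -0.39 and 0.56, a median of 0.02 and a mean of 0.01 (camera, downward, Benjamini-Hochberg adjusted p = 0.829).

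Among markers of other cell types, 0 of the tested genes passed limma-trend. Of the fibroblast markers 0 of 8 passed, also when adjusted over the list alone, with FBLN1, PDGFRB, LUM and DCN at 0.75, -0.32, 0.27 and -0.16, a median of -0.01 and a mean of 0.06 (camera, downward, Benjamini-Hochberg adjusted p = 0.829). Of the Schwann and glial markers EGFR and S100B were high enough to test, at 0.32 and -0.26, and 0 of 12 epithelial and 0 of 12 immune markers were. The 13 mitochondrially encoded mRNAs were not analysed here.

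**Figure D3:**
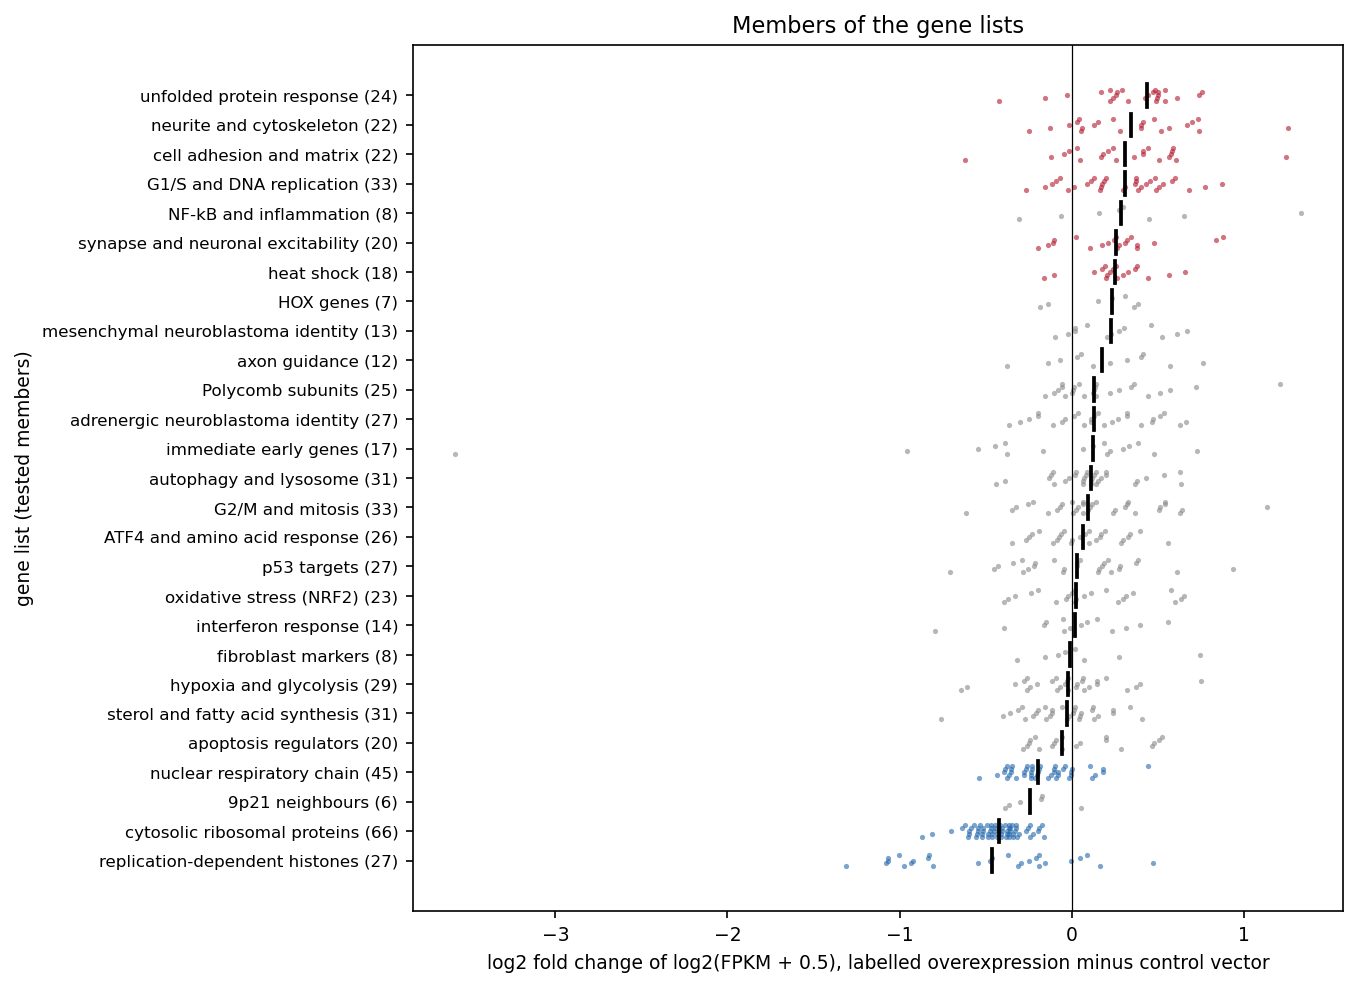
Log2 fold change of each tested member of the 27 lists with at least 5 tested genes, labelled overexpression minus control vector, with list medians as black bars. Red and blue mark the 9 lists past camera's adjusted p of 0.05 at the preset correlation, with medians from -0.46 for histones to 0.44 for the unfolded protein response; 0 passed with an estimated correlation.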

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

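Numbers of calls moved with the setting, while each of the 159 genes kept its direction wherever it was tested. In limma-trend with Benjamini-Hochberg adjustment, no filter on low values gave 0 calls, 0 higher and 0 lower (3538 at an unadjusted p under 0.05), and limma without the trend gave 0, 0 and 0 (2304 unadjusted). A minimum of 5 FPKM gave 339, 164 higher and 175 lower, rescaling to a common total 167 higher and 51 lower, array weights 265 with 149 higher, and a log2 fold change of at least 1 left 37, 21 higher and 16 lower. Leaving out single libraries gave 0 to 139 calls, 0 to 87 higher and 0 to 52 lower, fewer libraries being part of the construction. Of the alternatives chosen after the data were seen, limma-voom on the recovered fragments gave 127 calls, 79 higher and 48 lower, 95 of them shared with the main fit. The removed transcript length trend gave 163 calls, 48 higher and 115 lower, and the removed GC trend 383, 110 higher and 273 lower. The cause was not tested for the other settings. The pseudocount, robust moderation and median-of-ratios scaling kept the total within 147 to 178.

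Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at -0.0235, 0.105 and 0.119, and 4 of 6 libraries correlated best with their own number. With the replicate block the calls were 229, 98 higher and 131 lower, 151 of them shared with the fit without it. CDKN2B-AS1 did not pass in any setting, with log2 fold changes from 0.08 to 0.44. Of the 9 lists called, 8 passed camera in all 18 alternatives and the synapse list in 13. Robust moderation and the fold minimum do not enter camera and are left out of that number. With an estimated correlation 0 lists passed (8 at an unadjusted p under 0.05), and 0 in every alternative but the values rescaled to a common total, where 5 did at a Benjamini-Hochberg adjusted p of 0.0471 each. Fry called 13, all 9 among them, and 7 with the replicate block to 15 with the rescaled values. In the main fit its further lists, all upward, were NF-kB and inflammation, autophagy and lysosome, adrenergic neuroblastoma identity and axon guidance. Their Benjamini-Hochberg adjusted p in fry was 0.00455, 0.00479, 0.0198 and 0.0418. Medians of called lists moved too: that of the histones was -0.83 with a minimum of 5 FPKM, and that of the synapse list was 0.16 without a filter, 0.39 with rescaled values and 0.15 with the length trend removed. For named genes with a call, 462 of 797 values kept it and 335 lost it, and 0 reversed. For named genes without a call 57 of 1768 values passed, as did 7 of 321 values of lists without a call. Genes that are not named do not enter these numbers. Count models in DESeq2 and edgeR were planned for raw counts only and not run, since the table holds FPKM. The 127.08 to 353.42 fragments of CDKN2B-AS1 limit what can be seen of that RNA.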

Other observations

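The tests on ribosomal protein pseudogenes, on RNAs without a poly(A) tail and on genes overlapping CDKN2B-AS1, the gene ontology test and the HNRNP, cytoskeletal, TFPI2, SCG2, MTRNR2L and U1 genes were chosen after the results were seen.

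Genes outside the lists were among the rises, and those given here were singled out by their values, so they test no group. Of 23 tested HNRNP genes, which encode nuclear RNA-binding proteins, 21 had log2 fold changes above 0 and 4 passed limma-trend with Benjamini-Hochberg adjustment, HNRNPM at 0.69, HNRNPD at 0.76, HNRNPA2B1 at 0.52 and HNRNPF at 0.51. The nonmuscle myosin MYH10 rose from 14.98 ± 1.65 to 26.2 ± 2.08 FPKM, and the spectrins SPTBN1 and SPTAN1 and the actin ACTG1 had 0.87, 0.69 and 0.56. TFPI2, a protease inhibitor of the matrix, and SCG2, a secretogranin of dense-core vesicles, had 0.87 and 0.99. Of 1037 biological process terms of 15 to 500 genes, camera at the preset correlation with Benjamini-Hochberg adjustment called 27 up and 28 down, and 0 with an estimated correlation. Mitochondrial translational elongation was down, with a median of -0.15 over 88 genes (camera, Benjamini-Hochberg adjusted p = 2.02e-07, and adjusted p = 0.506 with an estimated correlation), and regulation of cell shape was up, with a median of 0.20 over 83 genes (adjusted p = 0.00483, and adjusted p = 0.506 with an estimated correlation). Axon guidance (91 genes), G2/M transition (113) and mitotic cell cycle (110) were up as terms, with medians of 0.19, 0.15 and 0.15. Camera's Benjamini-Hochberg adjusted p for those terms was 0.0350, 0.0367 and 0.0433, and 0.506 each with an estimated correlation. The fixed lists of axon guidance and of G2/M and mitosis, with other and fewer genes, did not pass.

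Some copies of the mitochondrial ribosomal RNA gene in the nuclear genome were among the falls, and no test of them as a group was run. Of 9 tested MTRNR2L genes 8 had log2 fold changes below 0 and 3 passed limma-trend with Benjamini-Hochberg adjustment, MTRNR2L1 at -0.60, MTRNR2L6 at -0.64 and MTRNR2L8 at -0.53. Their fragments cannot be told from those of the mitochondrial genome in this table.

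The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 159 genes and the highest of the others 1, and 1 split, the real one, gave as many. For the lists the real split gave 9 and the highest of the others 4, and again 1 split gave as many.

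CDKN2B-AS1 differed little between the groups. A candidate explanation is that fragments of the vector's RNA were assigned to genes that overlap it. If the control level of CDKN2B-AS1 had been added to the 6 overlapping genes other than CDKN2A, their depth-scaled sum would have risen by 1.02 on the log2 scale. Its log2 ratio was -0.10 (range over libraries -0.78 to 0.57), so the sum did not rise by that amount. This does not decide the explanation, because the sum rested mostly on a protein-coding gene of 622 bases that begins before the start of CDKN2B-AS1. That gene held 157.58, 116.33 and 261.42 fragments in control vector replicates 1, 2 and 3, against at most 15.42 in any other of these genes. How much of its sequence CDKN2B-AS1 covers was not tested. For CDKN2A, adding the control level of CDKN2B-AS1 would have given 0.30, and the log2 ratio was -0.34 (-0.93 to 0.12). This stays open too, because the added amount is 23.5% of the control level of CDKN2A and a fall of CDKN2A itself would hide it. A smaller rise in the cells, or vector RNA that the gene annotation does not cover, stays open as well and was not tested.

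The ribosomal protein list was called lower by camera at its preset correlation, with all 66 members below 0, though 44 of 66 did not pass singly and the list did not pass with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0939). A length or GC bias of the libraries may lower short messages. With the length trend removed the list's median was -0.44 (95% bootstrap interval -0.48 to -0.40) and with the GC trend removed -0.51 (-0.55 to -0.46). These intervals cover the draw of genes only, with the libraries held fixed. In these libraries, neither trend as fitted was the whole cause. Fragments moving to pseudogene copies are argued against as the whole cause, because 170 of 192 tested ribosomal protein pseudogenes were below 0, with a median of -0.33 (-0.37 to -0.28). Pseudogene values may hold fragments shared with the ribosomal protein genes, so a smaller move stays open. An effect of the vector or of CDKN2B-AS1 on these messages stays open as a hypothesis, beside differences between the cultures or library preparations of the groups, which the labels do not describe.

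The histone list was called lower and the G1/S and DNA replication list higher by camera at its preset correlation, though 19 of 27 and 30 of 33 members did not pass singly and neither list passed with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0939 and adjusted p = 0.0957). Fewer cells in S phase could lower histone messages, but the replication list had a median of 0.31 (95% bootstrap interval 0.17 to 0.43). It had 27 members above 0 and 6 below, against the shared fall predicted under that explanation. The list also holds G1/S genes, and the share of cells in S phase was not measured, so fewer such cells are not ruled out. With the transcript length trend removed the histone median was -0.49 (-0.86 to -0.26), which argues against that trend as the whole cause. These intervals cover the draw of genes only and carry no spread between libraries. Lower capture of RNAs without a poly(A) tail may contribute: 6 rows of RN7SK, RN7SL1, RMRP and RPPH1 had a median of -0.67 and a range of -0.85 to 0.24. That test stays open because RMRP and RPPH1 were low and stand on overlapping rows, though RN7SK passed limma-trend at -0.72 (Benjamini-Hochberg adjusted p = 0.0332) and 15 of 16 tested U1 RNA copies, which share fragments, lay below 0. An effect of the vector on histone messages was not tested separately.

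FOS was also tested against its relatives and with each library left out, the latter chosen after its values were seen, and these results are given as values and not weighed. The other 16 immediate early genes had a median log2 fold change of 0.16 (95% bootstrap interval -0.38 to 0.30), and FOS had -3.87 to -3.11 with any library left out.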
